A study of Mus musculus with 6 samples.

How the data were processed

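The series holds RNA sequencing of MC3T3-E1 cells, 3 control and 3 glucocorticoid (GC) libraries taken after 12 hours. Per the labels' protocols, total RNA was extracted with TRIzol, mRNA was fragmented with divalent cations, and libraries were made with the NEBNext Ultra RNA kit. The labels' design text calls the replicates biological. The submitters' processing notes list HISAT2, HTSeq and DESeq2 without versions and the genome build mm10; the annotation release and the strand setting are not given in the sources used here. Groups and replicate numbers were taken from the sample titles.

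The deposited table held FPKM values made by the authors, 54532 rows by 6 libraries, and its header names no unit. The unit was found from the values. Multiplied by the exon length of the gene in GENCODE M21 (mm10) and by a depth per library, the values were whole within 0.0001 in all 6 libraries for 25620 of 26481 rows with a unique name and a value above 0, or 96.7%. These whole numbers are called recovered reads here. The depths the authors had divided by differed by at most 0.0428% from median-of-ratios factors of the recovered reads, so the deposited FPKM already carried a scaling between libraries. Recovered reads per library summed to 16893488, 16110132 and 15902270 in control 1 to 3 and 17952310, 16860876 and 17109831 in GC 1 to 3. The deposited FPKM summed to 313024, 297065 and 301720 in control and 342672, 288876 and 318034 in GC. In 27783 rows every library was at 0. Names were shared by 203 rows; the row with the highest mean kept the symbol. In 11 rows the name had become a date, 38 rows were matched through an older symbol and 551 were not matched to the annotation.

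The main test was limma-trend (limma 3.58.1 in R 4.3.3; eBayes with trend and robust options) on log2(FPKM + 1) for the 11730 rows with at least 1 FPKM in at least 3 libraries, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The count tests planned as the main and an alternative test, edgeR and DESeq2, were not run because the deposited unit is not counts; limma-trend was the test set for that case. Recovered reads existed for 11685 tested rows. limma-voom on them was an alternative, and they show the depth behind single values.

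Before the data were examined, 33 gene lists were fixed from textbook knowledge. Lists with at least 5 tested members, 27 of them, were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. With the preset correlation 11 lists passed, 7 higher and 4 lower. With an estimated correlation none passed in limma's camera, the lowest adjusted p was 0.146, and 2 lists had an unadjusted p under 0.05. The p53 targets lost their call (camera, adjusted p = 0.000226 to 0.146) at an estimated correlation of -0.06, which is under the preset one. Losing a call in this setting is therefore no proof of correlation between the genes of a list. fry, which asks whether genes of a list move one way without comparing them with other genes, passed 10 lists, and 1 list, the p53 targets, with the replicate block. Lists past fry but not camera were BMP and TGF-beta signalling (fry, adjusted p = 0.0200), osteoclast regulators (0.0107), receptor and steroid handling (0.0107) and circadian clock (0.0200).

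The genes named were fixed by rule before the data were examined. They are the 12 highest and 12 lowest log2 fold changes among genes past the threshold whose groups do not overlap and whose mean is at least 1 FPKM, leaving out predicted genes and pseudogenes. To these come, in each list, up to 4 members past the threshold or, where none passed, the 2 with the highest mean, and 18 fixed genes. Not all of these are named in the text, and the results of some are not reported here. Of the 92 named genes tested, 11 overlap another tested gene, so part of their reads is uncertain. A few genes outside the rule are said to have been named after their values were seen.

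Whether replicate numbers pair the libraries was checked on deviations from the group means across the tested genes. The correlation between the control and the GC library of the same number was 0.511, 0.248 and 0.383, and the highest between different numbers was 0.0233. Each exceeded 0.1, so blocked values are given for named genes and lists whose call or number of called members they change. Deviations from a group mean cancel within the group, so positive values for the same number make those for different numbers tend to be negative. That contrast is therefore no evidence of its own. With so few libraries the check cannot show that cultures were shared, and the labels say nothing of shared cultures. The first principal component held 41.3% of the variance and the second, 26.5%, set both replicate 1 libraries apart. On the first, GC replicate 2 (-4.60) lay nearer control replicate 1 (-7.57) than GC replicate 1 (29.9) or GC replicate 3 (17.5). No replicate pair was alike within sampling noise: the mean chi-square per gene between libraries of a group was at least 8.70.

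The fit was tested on simulated data: reads were drawn for 11685 genes at the real depths, with 200 genes changed in each of 5 draws. For the comparison of GC with control it called 23.6% of the genes changed 1.5-fold, 79.4% of those changed 2-fold and 90.6% of those changed 3-fold, and 6.71% of its calls were false. camera called 20 of 20 simulated lists of 20 genes raised 1.5-fold and 0 of 20 unchanged lists at an unadjusted p under 0.05. These reads were drawn for each gene apart, without the correlation between genes or any pairing of the real libraries. The simulation therefore gives no rate of false list calls for the real data. In the 9 other splits of the real libraries 2 to 7 of the 27 lists passed. Each of these splits mixes control and GC libraries unequally, so part of any treatment difference stays and this gives no such rate either. With an estimated correlation none of the 11 list calls held, though for the p53 targets the estimated correlation was under the preset one.

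Alternatives were TMM, upper-quartile and library total scaling computed from the recovered reads, other filters, a pseudocount of 0.1 FPKM, the replicate block, limma-voom, and leaving out each library. Added after seeing the data were removal of the trend of each library over exon length and base composition (loess; 99.6% of tested genes had both), the same with the block, leaving out both replicate 1 libraries, and voom with the block. Figures were drawn with matplotlib 3.10.9.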

Results

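Messenger RNA was measured by sequencing in MC3T3-E1 cells, a pre-osteoblast line from mouse skull bone. The cells were kept under normal conditions or with glucocorticoid (GC) for 12 hours, with 3 control and 3 GC libraries. The labels name neither the glucocorticoid nor its dose, and they place the study in work on osteoblast death under glucocorticoid. The deposited values were FPKM, read numbers scaled for gene length and library depth. The libraries held between 15902270 and 17952310 recovered reads, and 1 FPKM at the median gene length stood for at least 64.9 reads. Of 54532 rows, 11730 had at least 1 FPKM in at least 3 libraries and were tested. Fold changes are differences of log2(FPKM + 1) and understate the change of genes with low values.

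GC-treated cells held more RNA of well-known glucocorticoid-induced genes than control cells. Tsc22d3, which encodes the anti-inflammatory protein GILZ, rose from 28.4 ± 1.43 FPKM in control to 162 ± 14.4 FPKM in GC (SD, n = 3 each), a log2 fold change of 2.47 ± 0.12 (SE). Sgk1, a kinase that regulates ion transport, rose from 24.9 ± 1.98 to 130 ± 15.5 FPKM, a log2 fold change of 2.33. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose from 12.5 ± 0.851 to 29.9 ± 1.75 FPKM, and the clock gene Per1 rose from 5.15 ± 1.18 to 14.4 ± 2.56 FPKM. The adjusted p-values by limma-trend were 0.000371 for Tsc22d3, 0.000389 for Sgk1, 0.00289 for Fkbp5 and 0.0174 for Per1. Of the 16 tested members of the glucocorticoid-induced list, 8 rose, none fell and 8 did not pass, while with the replicate number as a block 10 rose and 1 fell. The other members that rose, named after their values were seen, were Dusp1, Pdk4, Glul and Cebpd, with log2 fold changes of 0.61, 0.74, 0.96 and 0.87. When adjusted over the list alone, 12 members rose and 1 fell. The list as a group was higher in GC (camera, adjusted p = 6.61e-14, median log2 fold change 0.56). With an estimated correlation between genes the adjusted p = 0.146.

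Tsc22d3 (ENSMUSG00000031431.13) lies on the minus strand of chromosome X from 140539528 to 140600659 in mm10. Sgk1 (ENSMUSG00000019970.15) lies on chromosome 10 from 21882184 to 21999903, Fkbp5 (ENSMUSG00000024222.17) on chromosome 17 from 28399094 to 28517527, and Per1 (ENSMUSG00000020893.17) on chromosome 11 from 69095217 to 69109960. The values are sums over all exons of each gene, untranslated regions included. In the panels of single genes, each GC library lies above each control library for all 4 of these genes.

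**Figure D1:**
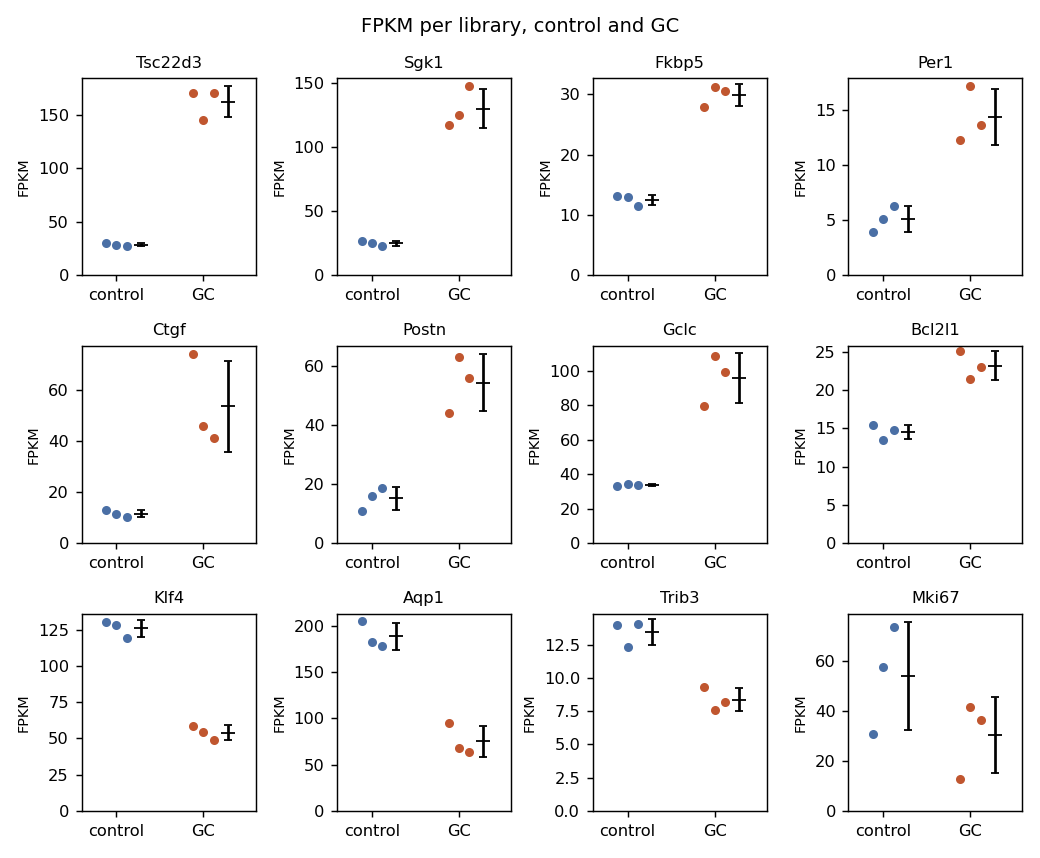
FPKM of 12 genes in each library, with the 3 control libraries in blue and the 3 GC libraries in orange; the black marks are the group mean and SD. Tsc22d3 averaged 28.4 FPKM in control and 162 FPKM in GC, Klf4 averaged 126 and 54.0 FPKM, and the Mki67 values of the groups overlapped.

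Across all tested genes, 227 differed between GC and control at an adjusted p under 0.05, with 127 higher and 100 lower in GC. At least 2-fold changes on the log2 scale were found for 62 of them. In all 227 the 3 GC libraries lay wholly above or below the 3 control libraries, which held for 25.6% of all tested genes. By chance it is expected for 10%, a value that takes no account of any pairing by replicate number. Among the genes named here, the largest rises after Tsc22d3 and Sgk1 were those of Ctla2a, a cathepsin inhibitor (0.429 ± 0.0700 to 5.99 ± 1.598 FPKM), Rgcc, a regulator of the cell cycle (6.74 ± 0.622 to 31.9 ± 3.23 FPKM) and Ctgf, a matricellular growth factor (11.6 ± 1.33 to 53.5 ± 17.8 FPKM). Their log2 fold changes were 2.26 ± 0.19, 2.09 ± 0.11 and 2.07 ± 0.21. Postn, Hspb7, Jazf1, Ptx3 and Mmp13 rose by log2 fold changes of 1.79, 1.67, 1.65, 1.63 and 1.54. Ceacam10 was listed at 0 in all 3 controls and reached 2.22 ± 0.352 FPKM in GC. Ctla2a and Ceacam10 have close paralogs, so their reads are uncertain.

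The fitted fall of greatest size belonged to mt-Tv, a mitochondrial tRNA, and the next to the microRNA gene Mir7237, but at most 7 and 3 reads of them were seen in any library. Among longer genes, Afap1l2, an adaptor of the actin skeleton, fell from 12.3 ± 0.599 to 3.79 ± 0.249 FPKM, a log2 fold change of -1.47 ± 0.10. Aldh1l2, a mitochondrial folate enzyme, fell from 20.1 ± 0.666 to 6.96 ± 1.97 FPKM. Aqp1, a water channel, fell from 189 ± 14.5 to 75.2 ± 16.8 FPKM, and Klf4, a transcription factor, fell from 126 ± 5.68 to 54.0 ± 5.15 FPKM. Spon2, Asic1, Itgb7, Anxa8 and Dagla fell as well, with log2 fold changes of -1.33, -1.33, -1.30, -1.24 and -1.21. The keratin gene Krt14 fell from 1.93 ± 0.426 to 0.0895 ± 0.0845 FPKM.

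The test was limma-trend with Benjamini-Hochberg adjustment over the 11730 genes. Libraries of the same number deviated alike from their group means, which does not show that they shared a culture. With the replicate number as a block 1051 genes passed, with 465 higher and 586 lower, all 227 among them. Leaving out 1 library gave 42, 33 and 33 genes without control replicate 1, 2 and 3, and 87, 1238 and 14 genes without GC replicate 1, 2 and 3. Of 57 named genes past the threshold, 30, 35, 33, 21 and 43 lost it without control replicate 1, 2 and 3 and GC replicate 1 and 3, and none changed sign.

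**Figure D2:**
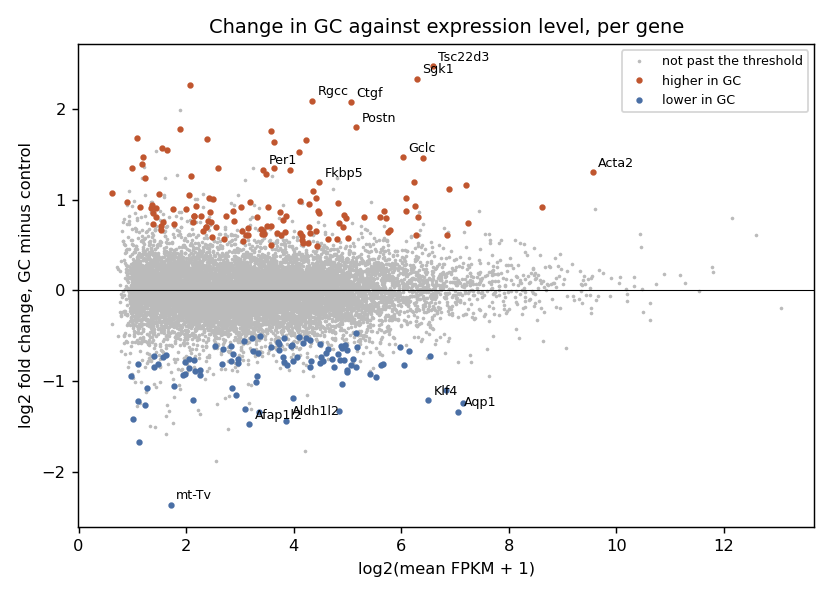
Log2 fold change of each of the 11730 tested genes, GC minus control, against log2 of its mean FPKM plus 1. The 127 genes past the threshold that were higher in GC are orange, the 100 lower ones are blue, and Tsc22d3 has the highest fold change at 2.47.

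Of 24 tested matrix and collagen processing genes, 4 rose, none fell and 20 did not pass, with 14 positive and 10 negative fold changes. Postn, a matricellular protein of bone, went from 15.2 ± 3.89 to 54.4 ± 9.66 FPKM, and Thbs1, another matricellular protein, from 7.79 ± 0.499 to 24.5 ± 3.84 FPKM. Thbs2 and Loxl1, which encodes an enzyme of elastin crosslinking, rose by 0.64 and 0.69 on the log2 scale. The list passed (camera, adjusted p = 0.0171), with an adjusted p = 0.480 with an estimated correlation and an adjusted p = 0.298 without GC replicate 2. There were 6 rises and no fall adjusted over the list alone, and also 6 and none with the replicate block.

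Of 13 tested matrix proteases and inhibitors, 3 rose and 1 fell. The collagenase gene Mmp13 went from 0.597 ± 0.229 to 3.67 ± 0.785 FPKM and Adamts1 from 5.52 ± 0.694 to 15.0 ± 3.43 FPKM. The protease inhibitor gene Timp3 fell from 40.4 ± 4.11 to 21.5 ± 4.16 FPKM. The list was higher in GC (camera, adjusted p = 0.00758) and lost that without GC replicate 1 (0.0710) and GC replicate 2 (0.147). The adjusted p = 0.480 with an estimated correlation, and 4 members rose and 1 fell both adjusted over the list alone and with the replicate block.

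Of 15 tested cytoskeletal and YAP or SRF targets, 4 rose, none fell and 11 did not pass. They were Ctgf, Acta2, which encodes smooth muscle actin (429 ± 13.7 to 1077 ± 245 FPKM), Myl9, a myosin light chain (89.4 ± 4.48 to 204 ± 45.3 FPKM) and Cyr61 (52.1 ± 9.79 to 99.5 ± 12.8 FPKM). Of these 15, 7 rose and 1 fell adjusted over the list alone, and 5 rose with the replicate block. The list was higher in GC (camera, adjusted p = 0.000620), with an adjusted p = 0.480 with an estimated correlation. Acta2 shares sequence with other actin genes, so part of its reads is uncertain.

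The series title names apoptosis, and no pro-apoptotic gene passed the test. None of 29 tested members rose or fell, adjusted over all genes or adjusted over the list alone, and none by limma-voom, while 3 had an unadjusted p under 0.05 by limma-trend. Bax averaged 91.1 ± 7.30 FPKM in control and 101 ± 22.1 FPKM in GC, and Bcl2l11, which encodes BIM, 4.09 ± 0.552 and 3.13 ± 0.311 FPKM. Their adjusted p-values by limma-trend were 0.773 and 0.244. The death receptor gene Fas, named after its values were seen, averaged 5.62 ± 1.03 FPKM in control and 10.6 ± 2.87 FPKM in GC without passing. Of the 29 members 16 had positive and 13 negative fold changes. In the simulation the fit called 23.6% of genes changed 1.5-fold, so the lack of calls is weak evidence of no change. The list did not stand apart from other genes (camera, adjusted p = 0.597, median log2 fold change 0.05), and with the replicate block 1 member rose. Of 15 tested anti-apoptotic genes, Bcl2l1, which encodes BCL-XL, rose from 14.5 ± 0.952 to 23.2 ± 1.88 FPKM with an adjusted p of 0.0317, and adjusted over the list alone it was again the 1 member that rose. Bcl2 averaged 1.38 ± 0.0495 and 1.497 ± 0.164 FPKM, and the list did not pass (camera, adjusted p = 0.617).

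Of 15 tested p53 targets, Btg2 and Plk2 rose, none fell and 13 did not pass. Btg2, an antiproliferative gene, went from 9.26 ± 0.479 to 16.5 ± 0.596 FPKM, and Plk2, a kinase, from 8.94 ± 0.571 to 13.0 ± 0.425 FPKM. The fold change was positive for 12 of the 15 and the list was higher in GC (camera, adjusted p = 0.000226; adjusted p = 0.146 with an estimated correlation). Of the p53 targets 5 rose adjusted over the list alone, and 6 rose with the replicate block. Of 24 tested unfolded protein response genes, Trib3 fell from 13.5 ± 0.998 to 8.37 ± 0.879 FPKM, none rose, and the list did not pass (camera, adjusted p = 0.840), with a mean log2 fold change of -0.03 and a median of 0.06. The fall of Trib3 was also the only call adjusted over the list alone, and with the replicate block 2 members fell. The chaperone gene Hspa5 averaged 148 ± 5.94 and 160 ± 12.5 FPKM and Ddit3, which encodes CHOP, 11.9 ± 3.18 and 11.01 ± 0.171 FPKM. Ddit3 overlaps Mars and Gm4189 on the opposite strand, so its reads are uncertain.

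Genes that mark osteoblasts showed no change past the threshold in 13 tested members by limma-trend (camera, adjusted p = 0.840), while 4 had an unadjusted p under 0.05 and 1 rose by limma-voom. Col1a1, the main collagen of bone, averaged 1755 ± 47.8 FPKM in control and 1416 ± 226 FPKM in GC (limma-trend, adjusted p = 0.381). The transcription factors Runx2 and Sp7 averaged 10.3 ± 0.747 and 4.01 ± 0.0827 FPKM in control and 10.8 ± 1.59 and 4.95 ± 0.938 FPKM in GC, and Spp1 1216 ± 107 and 1126 ± 175 FPKM. Of the 13, 2 rose and 2 fell adjusted over the list alone, and with the replicate block 1 rose and 2 fell. Alpl was listed at 0 in all libraries except GC replicate 3, which held 0.0288 FPKM, and Tnfsf11, which encodes RANKL, was listed at 0 in all 6. Bglap, the osteocalcin gene, was below the filter, with 0.101, 0.824 and 0.412 FPKM in control and 0.476, 1.43 and 0.938 FPKM in GC. Runx2 overlaps Supt3 and Runx2os1 on the opposite strand and Spp1 overlaps Gm42793, so part of their reads is uncertain.

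Tnfrsf11b, which encodes the RANKL decoy receptor osteoprotegerin, rose from 3.47 ± 0.240 to 6.25 ± 0.513 FPKM. It was 1 of 6 tested osteoclast regulators, and 5 did not pass (camera for the list, adjusted p = 0.265; 2 rose adjusted over the list alone). Among 19 tested BMP and TGF-beta signalling genes, the BMP-responsive genes Id2 and Id3 rose from 12.0 ± 0.680 to 26.9 ± 4.38 FPKM and from 43.5 ± 4.29 to 89.9 ± 16.6 FPKM. That list did not pass (camera, adjusted p = 0.265), 4 rose and 3 fell adjusted over the list alone, and 3 rose and 1 fell with the replicate block. None of 14 tested Wnt targets and ligands passed by limma-trend or limma-voom, and 3 had an unadjusted p under 0.05 (camera, adjusted p = 0.0626). The Wnt list passed without control replicate 3 (0.0327) and without GC replicate 2 (0.0207) at the preset correlation, and with all 6 libraries it had an adjusted p = 0.511 with an estimated correlation. Among the Wnt targets 2 fell adjusted over the list alone, and 3 fell with the replicate block. Of the Wnt antagonists only 3 were tested, too few for a list test, and none passed over all genes (2 rose adjusted over the list alone and with the replicate block). The highest of them, Dkk3, averaged 154 ± 5.74 and 238 ± 24.4 FPKM with an adjusted p by limma-trend of 0.0623, or 0.0228 with the replicate block.

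Among 7 tested adipocyte genes, Pnpla2, a triglyceride lipase, fell from 9.99 ± 0.247 to 6.67 ± 0.593 FPKM and Adipor2, an adiponectin receptor, fell from 29.1 ± 2.91 to 17.7 ± 2.61 FPKM. The list was lower in GC (camera, adjusted p = 0.00284; adjusted p = 0.480 with an estimated correlation), 4 fell adjusted over the list alone, and 3 fell with the replicate block. The list of 21 tested cholesterol synthesis genes was lower in GC (camera, adjusted p = 0.000177; adjusted p = 0.472 with an estimated correlation), with 20 negative fold changes and a median of -0.21. No single member passed over all genes by limma-trend, 9 had an unadjusted p under 0.05, 2 fell by limma-voom, 5 fell adjusted over the list alone, and 5 fell with the replicate block. Srebf2, the transcription factor of the pathway, averaged 69.5 ± 2.14 FPKM in control and 46.3 ± 6.42 FPKM in GC with an adjusted p by limma-trend of 0.0680, or 0.0210 with the block.

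Glycolysis and hypoxia genes were lower as a list (camera, adjusted p = 0.00284; adjusted p = 0.480 with an estimated correlation). Of 18 tested members 16 had negative fold changes, with a median of -0.21, and none passed over all genes by limma-trend, while 5 had an unadjusted p under 0.05 and 3 fell by limma-voom. Of these, 4 fell adjusted over the list alone and 3 fell with the replicate block. Pgk1, a highly expressed member, averaged 683 ± 71.0 and 623 ± 124 FPKM. The 22 tested autophagy and lysosome genes were higher as a list (camera, adjusted p = 0.00722; adjusted p = 0.480 with an estimated correlation), with 17 positive fold changes and no member past the threshold over all genes by limma-trend, while 10 had an unadjusted p under 0.05 and 2 rose by limma-voom. Ctsd, a lysosomal protease, averaged 123 ± 14.9 and 172 ± 26.6 FPKM. Of the lysosome list 2 rose adjusted over the list alone, and 4 rose with the replicate block, Ctsd among them.

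Transcripts of the mitochondrial genome were higher as a list (camera, adjusted p = 0.00226; adjusted p = 0.480 with an estimated correlation), with 11 of 13 positive. None passed alone by limma-trend, while 5 had an unadjusted p under 0.05 and 1 rose by limma-voom. mt-Co1, a subunit of cytochrome oxidase, averaged 4913 ± 154 and 7526 ± 532 FPKM. Mitochondrial genes took 1.96%, 2.27% and 2.32% of reads in the controls and 2.60%, 2.96% and 2.99% in GC. The list call ended without control replicate 1 (0.0606) and with no filter (0.0647). Of its members 3 rose adjusted over the list alone, and 2 rose with the replicate block.

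Libraries also differed by gene length and base composition. In the quintile of genes with the shortest exons the median deviation from the mean over libraries was 0.20 in GC replicate 1 and 0.12 in GC replicate 3, and in the quintile with the longest it was -0.20 and -0.09. GC replicate 2 went the other way, from -0.15 to 0.09, and the controls lay between -0.08 and 0.11 in these quintiles. By base composition the replicate 1 libraries went together. In the quintile lowest in G and C bases control replicate 1 lay at -0.13 and GC replicate 1 at -0.14, the other libraries between 0.02 and 0.15. In the highest quintile they lay at 0.08 and 0.07, the others between -0.09 and 0.03. Whether this bears on the correlation by replicate number was not tested. With the trend over length and base composition removed, an alternative chosen after seeing the data, 544 genes passed and the mitochondrial list did not (adjusted p = 0.0906).

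**Figure D3:**
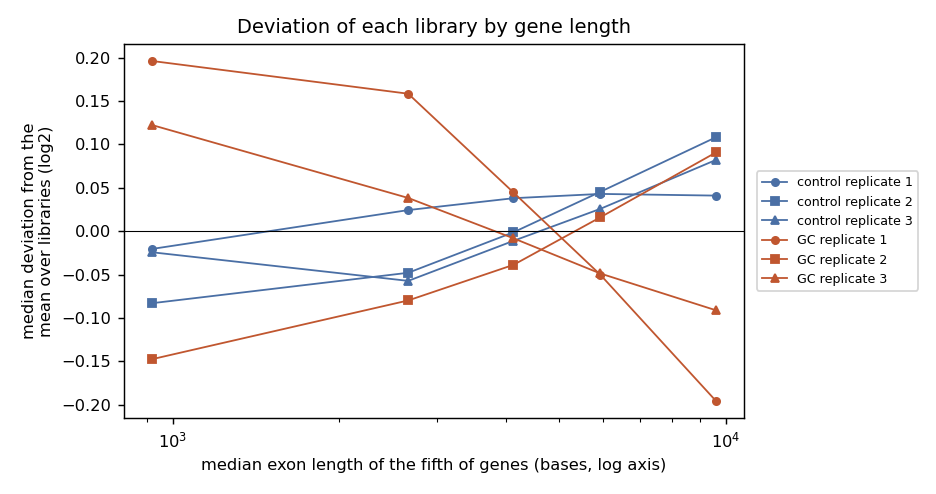
Median deviation of each library from the mean over the 6 libraries, on the log2 scale, in quintiles of the genes ordered by exon length (log axis). In the quintile of shortest genes GC replicate 1 lies at 0.20 and GC replicate 2 at -0.15.

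Of 21 tested oxidative stress genes, Gclc, the catalytic subunit of glutathione synthesis, rose from 33.7 ± 0.746 to 95.7 ± 14.6 FPKM, and 20 did not pass (camera, adjusted p = 0.617; 1 rose and 2 fell adjusted over the list alone, and likewise with the replicate block). No member of the heat shock list (10 tested, camera adjusted p = 0.197) or of the ribosomal protein list (32 tested, camera adjusted p = 0.1001) passed by limma-trend. Unadjusted p-values under 0.05 were found for 1 heat shock gene and no ribosomal gene, and by limma-voom 1 heat shock gene and no ribosomal gene rose. Cryab, a small heat shock protein gene, averaged 62.0 ± 3.47 and 99.7 ± 13.7 FPKM, with an adjusted p by limma-trend of 0.0537, or 0.0175 with the replicate block. Cryab overlaps Hspb2 on the opposite strand. At the preset correlation the ribosomal list passed without GC replicate 2 (7.66e-06), and the sign of its median turned without GC replicate 1. With all 6 libraries that list had an adjusted p = 0.904 with an estimated correlation. Among heat shock genes 1 rose, and among ribosomal genes none did, adjusted over the list alone. With the replicate block 1 heat shock gene rose and 1 fell.

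Immediate early genes were lower as a list (camera, adjusted p = 0.0351; adjusted p = 0.555 with an estimated correlation). Klf4, Egr2 and Egr3 fell, and 12 of 15 did not pass. Egr2 and Egr3, transcription factors induced by growth signals, went from 7.09 ± 1.005 to 3.63 ± 0.659 FPKM and from 2.71 ± 0.300 to 1.23 ± 0.131 FPKM. The same number, 3, fell adjusted over the list alone, and 4 fell with the replicate block. The list call ended without control replicate 1 (0.0580), GC replicate 2 (0.218) and GC replicate 3 (0.0626), and with the replicate block and the length and base composition trend removed together (0.0706).

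None of 32 tested cell cycle genes passed by limma-trend or limma-voom, 6 had an unadjusted p under 0.05, and 23 had negative fold changes (camera, adjusted p = 0.0626, median -0.14). With the replicate block the list was lower in GC (adjusted p = 0.0329; adjusted p = 0.563 with an estimated correlation) and 3 members fell. The list passed in 7 of 16 alternatives at the preset correlation, without GC replicate 1 (0.0173) among them, and adjusted over the list alone no member passed. The proliferation marker Mki67 held 30.8, 57.5 and 73.5 FPKM in control replicates 1 to 3 and 12.9, 41.5 and 36.3 FPKM in GC. Each GC value of Mki67 was below the control value of its number, with an adjusted p by limma-trend of 0.380 without the block and 0.0228 with it.

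Among 13 tested inflammatory mediators, the chemokine gene Cxcl12 and the adhesion gene Vcam1 rose from 13.9 ± 1.28 to 23.1 ± 1.83 FPKM and from 14.9 ± 0.802 to 21.8 ± 0.394 FPKM. That list did not pass (camera, adjusted p = 0.840), its median of -0.03 and mean of 0.01 differed in sign, and 2 rose and 1 fell both adjusted over the list alone and with the replicate block. None of 12 tested interferon-stimulated genes passed by limma-trend or limma-voom, and 3 had an unadjusted p under 0.05 (camera, adjusted p = 0.0626), none passed adjusted over the list alone, and 1 rose with the replicate block. Ifi35, an interferon-induced gene, averaged 6.02 ± 0.444 and 8.72 ± 1.63 FPKM, with an adjusted p by limma-trend of 0.141, or 0.0482 with the replicate block. The interferon list passed without control replicate 2 (0.00941), control replicate 3 (0.0371) and GC replicate 1 (0.0213), and in 5 of 16 alternatives in all, each at the preset correlation. With all 6 libraries it had an adjusted p = 0.480 with an estimated correlation. Among 8 tested IGF axis genes the growth factor gene Igf1 rose from 0.978 ± 0.0994 to 2.46 ± 0.319 FPKM, the 1 call also adjusted over the list alone, and 2 rose with the replicate block (camera for the list, adjusted p = 0.840). None of 14 tested circadian clock genes passed by limma-trend (camera, adjusted p = 0.0731), while 6 had an unadjusted p under 0.05 and 1 rose and 2 fell by limma-voom. The clock list had 1 up and 3 down adjusted over the list alone, and 1 up and 3 down with the replicate block. Tef, a clock output factor, averaged 32.2 ± 0.412 and 24.8 ± 2.38 FPKM, with an adjusted p by limma-trend of 0.119, or 0.04765 with the block.

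The glucocorticoid receptor gene Nr3c1 averaged 22.2 ± 2.57 FPKM in control and 16.5 ± 3.06 FPKM in GC, a log2 fold change of -0.42 ± 0.16. Its adjusted p by limma-trend was 0.204 without the block and 0.0305 with it, and the values of Nr3c1 in the groups did not overlap. None of the 9 tested genes of receptor and steroid handling passed by limma-trend or limma-voom, also adjusted over the list alone, 1 had an unadjusted p under 0.05, and 1 fell with the replicate block (camera, adjusted p = 0.265). Of these, Hsp90ab1, a chaperone of the receptor, averaged 807 ± 72.2 and 677 ± 60.7 FPKM.

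Markers of other cell types were sparse. Of 10 endothelial, 11 muscle and 11 epithelial markers 1 each was tested, of 14 macrophage and osteoclast markers 2, and of 15 chondrocyte genes 2. Col2a1, the cartilage collagen, fell from 3.60 ± 0.447 to 1.21 ± 0.159 FPKM, and Krt14 was the epithelial gene that fell. Flt1 averaged 7.27 ± 0.843 and 5.47 ± 1.21 FPKM and Acta1 0.917 ± 0.198 and 1.48 ± 0.129 FPKM, without passing over all genes. The macrophage and osteoclast markers Lyz2 and Ctsk averaged 8.64 ± 2.05 and 35.0 ± 3.19 FPKM in control and 17.4 ± 3.35 and 53.05 ± 8.21 FPKM in GC. Their adjusted p-values by limma-trend were 0.0507 and 0.0886 without the block and 0.00304 and 0.0310 with it. Adjusted over the list alone, both macrophage markers rose and 1 chondrocyte marker fell. With 1 tested member each, the muscle, endothelial and epithelial lists allow no such adjustment, and the adjusted p by limma-trend over all genes was 0.217 for Acta1 and 0.244 for Flt1.

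**Figure D4:**
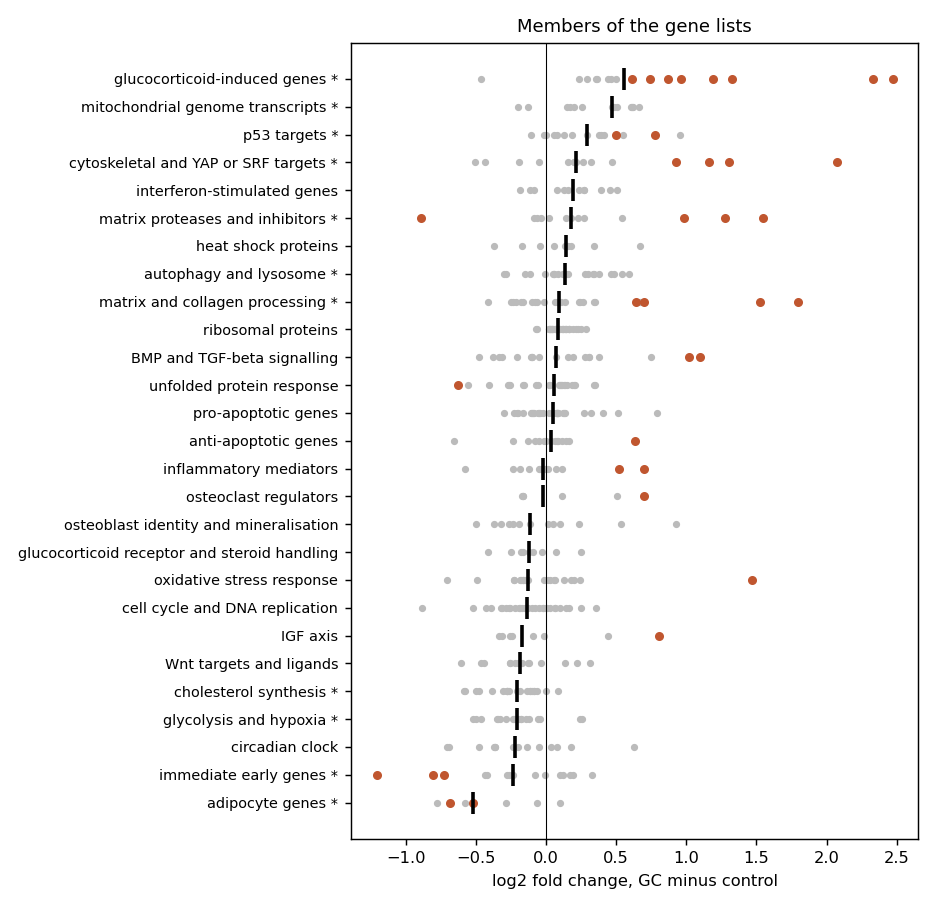
Log2 fold change, GC minus control, of the tested members of the 27 lists with at least 5 tested members; orange points passed the threshold over all genes, grey points did not, black bars are list medians, and an asterisk marks the 11 lists past the threshold by camera. The glucocorticoid-induced list has the highest median, 0.56, and the adipocyte list the lowest, -0.52.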

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

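Removal of the length and base composition trend, alone or with the replicate block, voom with the block, and leaving out both replicate 1 libraries were chosen after seeing the data. The counts of 227 changed, 127 higher, 100 lower and 62 at least 2-fold genes stayed within 1.5 times under TMM, upper-quartile and library total scaling, a mean filter and a pseudocount of 0.1. With no filter they were 17, 15, 2 and 16. The replicate block gave 1051, 465 and 586, and changed the call of the cell cycle list and of 12 named genes not called without it, Asns, Cryab, Ctsd, Ctsk, Dkk3, Ifi35, Lyz2, Mki67, Nr3c1, Psat1, Srebf2 and Tef. It changed no other call of a list or named gene, and added 8 falls among 25 further ATF4 targets. limma-voom gave 390, 194, 196 and 118, and with the block 2254, 867, 1387 and 162. Removing the trend gave 544, 299 and 245, and with the block 1321, 688 and 633. Leaving out both replicate 1 libraries gave 18, 13, 5 and 18. Leaving out 1 library gave 14 to 1238 changed, 12 to 467 higher, 2 to 771 lower and 14 to 125 at least 2-fold genes; the lowest came without GC replicate 3 and the highest without GC replicate 2. The cause of these differences was not tested. The 11 lists became 0 with an estimated correlation and 9 to 14 elsewhere. At the preset correlation the cell cycle list also passed with library total scaling (0.0475), no filter (0.00275), the trend removed (0.00438, or 0.00174 with the block) and without both replicate 1 libraries (0.0148). Without both, the interferon (0.0464) and circadian (0.0210) lists passed too, and with no filter the interferon list (0.0154). With the block and the trend removed, the mitochondrial and immediate early lists did not pass (0.0706 each). DESeq2 and edgeR were not run, since the values are FPKM.

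Of 57 named genes past the threshold, 10 kept their call in every alternative that tested them: Afap1l2, Fkbp5, Hspb7, Jazf1, Ptx3, Rgcc, Sgk1 and Tsc22d3 in 18, and Ceacam10 and Ctla2a in 14, as both miss the filter when a GC library is left out. No named gene or list past the threshold changed direction. The 46 changes of direction all lay in results past no threshold. For lists, direction is that of camera, which can turn while the median keeps its sign, as it did for the unfolded protein response (main median 0.06) and in most cases for the IGF axis (-0.17). With the trend removed, with or without the block, they were Ccnd1 (0.0076), Kremen1 (0.087), mt-Nd1 (-0.0086), Rplp0 (-0.033), Rps2 (-0.041) and the IGF list (median 0.054). Without both replicate 1 libraries they were Rplp0 (-0.041), Rps2 (-0.089) and the IGF list (-0.084). The osteoblast list had a median of 0.012 with no filter and with the mean filter, and the unfolded protein response list 0.058 with the block. Leaving out 1 library, log2 fold changes ranged from -0.00097 to 0.31 for Bax, -0.12 to 0.090 for Ccnd1, -0.18 to 0.12 for Ddit3, -0.14 to 0.058 for Hspa8, -0.18 to 0.031 for Pgam1, -0.076 to 0.23 for Rplp0, -0.15 to 0.22 for Rps2, -0.058 to 0.11 for Runx2 and -0.063 to 0.10 for Tnfrsf1a. For osteoblast identity the main median was -0.12. List medians ranged from -0.24 to -0.066 for the IGF axis, -0.028 to 0.033 for inflammatory mediators, -0.18 to -0.056 for osteoblast identity, -0.16 to 0.083 for oxidative stress, -0.033 to 0.059 for pro-apoptotic genes, -0.074 to 0.28 for ribosomal proteins and 0.0027 to 0.056 for the unfolded protein response. Depth limits short RNAs such as mt-Tv, whose call was lost with limma-voom.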

Other observations

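Of 9 genes known as targets of the transcription factor ATF4 or related to it, 7 fell and 2 did not pass. These 9 genes, and the tests that remove the length and base composition trend, were chosen after seeing the data. Atf5 fell from 84.0 ± 12.4 to 46.9 ± 5.48 FPKM (SD, n = 3 each), the amino acid transporter gene Slc7a5 from 114 ± 3.70 to 69.5 ± 9.10 FPKM, and Mthfd1l from 42.8 ± 2.34 to 27.4 ± 2.90 FPKM. Cars and Pck2 fell by 0.52 and 0.51 on the log2 scale, beside Aldh1l2 and Trib3. Psat1 averaged 137 ± 15.4 and 85.2 ± 15.5 FPKM and Asns 96.4 ± 8.77 and 65.9 ± 12.8 FPKM, with adjusted p-values by limma-trend of 0.0783 and 0.123, or 0.0138 and 0.0236 with the replicate block. Slc3a2, the partner of Slc7a5 and itself a known ATF4 target, rose from 89.7 ± 3.25 to 138 ± 4.42 FPKM.

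Lower ATF4 activity under GC is a hypothesis for the falls among the 9 genes. To test it, a list of other ATF4 targets was written before their values were seen. The list held mostly tRNA synthetases and enzymes of serine and proline synthesis. Cars and Psat1 of the 9 genes belong to the same pathways, so the list is not independent of them. Of its 25 tested members 24 had negative fold changes with a median of -0.32 ± 0.03 (bootstrap SE over members). Such errors, here and for the medians below, leave out the spread between libraries and treat the genes as independent. By limma-trend none passed alone, while 8 fell with the replicate block, 3 with the length and base composition trend removed and 10 with both. For this list, 1 of 3 in its family, the unadjusted p by camera was 7.73e-09, or 0.0688 with an estimated correlation, which misses 0.05. These genes also answer to other regulators, and ATF4 protein was not measured, so the hypothesis stays open. With the length and base composition trend removed the median of the 9 genes was -0.65 ± 0.06 against -0.63 ± 0.06 before, which argues against that trend as its whole cause.

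Mitochondrial genome transcripts were higher in GC with a median log2 fold change of 0.47 ± 0.14, and the list call at the preset correlation was lost at adjusted p = 0.480 with an estimated correlation. With the length and base composition trend removed the median was 0.26 ± 0.14 and the list also did not pass at the preset correlation (adjusted p = 0.0906), with a lower fold and a similar spread between members. With the trend removed 8 fold changes were positive and 5 negative, against 11 and 2 as deposited. The median stayed above the bound of 0.1 set before the test by little more than its error over members, which leaves out the spread between libraries. By that bound the trend is disfavoured as the whole of the rise, but the sign count leaves this weak. The trend may account for part of the rise. More mitochondria per cell was predicted to raise nuclear-coded respiratory chain genes as well. In 41 of these the median was 0.0809 ± 0.0215 as deposited, with 29 positive, and -0.0167 ± 0.0158 with the trend removed. Both lie far below the median of the mitochondrial list, so the prediction was not met. More mitochondria need not raise these genes, so the values argue only against a rise that both sets share. RNA quality was not tested.

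Set against other groupings of the 6 libraries, the real grouping gave 227 genes, 127 higher, 100 lower and 62 at least 2-fold, and each of the 9 other splits gave at most 1. In each of these counts 1 of 10 splits, the real one, was as large, and 10 splits are too few for a share under 0.05. Each other split mixes control and GC libraries unequally, so part of any treatment difference stays between its sides and the rest widens the spread within them. The counts of the other splits are thus not those of unchanged libraries. For gene lists the real split gave 11, the highest other gave 7, and 5 was the highest among the other splits that part all 3 pairs. The 6 splits left keep a control and a GC library of the same number together on each side. After the trend over length and base composition was removed, 92.5% of the 227 genes kept their call and sign. The 95% exact interval, 88.3 to 95.6, treats genes of the same libraries as independent. Removing the trend also let more genes pass, 544, so keeping a call is a weak test. The median absolute log2 fold change of the 227 went from 0.81 to 0.77, which argues against that trend as the cause of these changes as a whole. A response to glucocorticoid, the biological explanation the design names, is left open by the splits. The list of glucocorticoid-induced genes fixed beforehand was higher in GC (camera, adjusted p = 6.61e-14, or adjusted p = 0.146 with an estimated correlation). By fry its adjusted p = 0.000830, or 0.0566 with the replicate block, and 15 of its 16 tested members had positive fold changes. These values go with that explanation.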
